A study of Mus musculus with 9 samples.

How the data were processed

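RNA was profiled in 9 mouse libraries: 6 of B16F10, a melanoma line derived from C57BL/6 mice, and 3 of CD8+ T cells isolated with a kit from spleen. Per the labels, cells stood in medium for 5 h without or with 600 µM hypochlorous acid (HOCl), RNA came from a column kit as total RNA, and a service laboratory sequenced it on an Illumina platform. The titles gave the 4 groups: B16F10 untreated (3 libraries), B16F10 HOCl (3), T cell untreated (2) and T cell HOCl (1). Nothing says that the replicates came from separate cultures or mice, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries within a group agreed within counting noise: a chi-square of their counts per degree of freedom ran from 3.91 to 25.9 in B16F10 and was 447 between the 2 untreated T cell libraries, so each was counted once.

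The deposited unit was the raw count of reads per gene, not normalised, made by the authors. Per the submitters' processing notes, the tools were FastQC 0.11.8, STAR 2.7.1a, featureCounts 1.6.0 and DESeq2 1.22.2 with genome build mm10. The annotation release, the strand setting, any filters and the treatment of reads that map to several places are not given in the sources used here. Reads from near-identical copies (histones, Hspa1a and Hspa1b, Tgtp1 and Tgtp2, receptor V segments), from overlapping genes and from antisense partners therefore cannot be told apart. Each cell type also had the authors' deposited table of their own comparison, of which the log2 fold change and the adjusted p-value were used here only to set calls side by side. Those tables do not name their groups by treatment, so the signs were taken as deposited and an equal sign also rests on their order. Of the 54838 genes in the count files, 54809 were found by ID in GENCODE M21 and 29 were not. Symbols were GENCODE's, or the gene ID where none was found. Those of the deposited tables equalled GENCODE's for 54782 genes and differed for 27. Coordinates are GENCODE M21 on GRCm38 (mm10), 1-based.

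Library totals ran from 45.9 to 61.3 M counts in B16F10, were 49.9 and 52.1 M in untreated T cells, and 12.8 M in the T cell HOCl library. A gene at 0 in a library could stand at up to 3 counts, which was 0.0489 to 0.0654 counts per M (CPM) in the deeper libraries and 0.234 CPM in the T cell HOCl library. Folds against a group at 0 were computed from that floor per library, on the TMM scale of the test, and are given as lower bounds. These floors, and the 95% Wilson intervals of shares of counts, cover counting error only.

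The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined; additions made later are named as chosen after seeing the data. Each cell type was tested apart with edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr with group as the factor, TMM scaling, estimated dispersions, a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. The T cell test had 1 residual degree of freedom, from its 2 untreated libraries, and assumed that the single HOCl library varied like them. Its prior degrees of freedom were infinite at the median, against 8.08 in B16F10. For a typical gene, the quasi-likelihood spread was thus the trend fitted across genes and not the gene's own. The difference of the HOCl effect between the cell types was an interaction contrast over all 9 libraries, which share 1 estimate of the spread. CPM values are per M of the library's gene counts, as mean ± SD.

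Gene lists, 34 in all, covered stress responses, growth, metabolism, pigment, RNA quality and markers of T cells and of other cells a spleen preparation or a culture could hold. Lists with at least 5 tested members (3 for metallothionein) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera sets a list against the other genes. Beside it stand camera with the correlation estimated from the libraries, limma's fry, which asks whether a list moves on balance 1 way, and counts of members past the threshold. A symbol with 2 gene IDs stood for the ID with more counts. Named genes were, per cell type, the 8 largest rises and 8 largest falls among genes past the threshold with at least 50 mean counts in the higher group and CPM ranges that did not overlap. Model names, clone names and pseudogenes were left out. Added to these were 20 fixed stress genes, 4 pigment genes in B16F10 and 7 T cell genes in T cells. Each list gave up to 2 members per direction, and the difference between cell types 6 per direction.

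Alternatives were DESeq2's size factors, library totals without TMM, no filter, a filter of 1 CPM and 50 mean counts, glmTreat against a 1.5-fold change, DESeq2 1.42.0, all 9 libraries in 1 fit, the replicate number as a block, a prior count of 0.5, and each replicate left out. Without 1 untreated T cell library, T cell contrasts set 1 library against 1. They were fitted together with all B16F10 libraries, which alone gave the spread. Chosen after seeing the data were offsets for gene length and GC content (loess, span 0.5), a T cell test without mitochondrial genes, and a T cell test on T cell-restricted genes. The last were nuclear genes at 20 CPM or more in untreated T cells and under 1 CPM in both B16F10 groups, scaled among themselves. For the makeup of each library, B16F10-only genes were nuclear genes over 50 CPM in both B16F10 groups and under 1 CPM in untreated T cells. T cell-only genes were over 50 CPM in untreated T cells and under 1 CPM in untreated B16F10. Data handling and figures used Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

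The methods were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed by each of 4 known folds. Simulated HOCl libraries were drawn from the untreated means of their cell type. They lacked the makeup of the real T cell HOCl library, with which 32499 genes were tested. They therefore cannot show how many false calls the real T cell test and the test of the difference made. The B16F10 test (15684 genes) recovered 78% of 1.5-fold, 96% of 2-fold and 100% of 4-fold and 8-fold changes and called 10 unchanged genes. The T cell test (17340 genes) recovered 0% of 1.5-fold and 2-fold, 24% of 4-fold and 58% of 8-fold changes and called 1 unchanged gene. The test of the difference (21045 genes) recovered 0%, 4%, 58% and 84% of those folds and called 12 unchanged genes. In the simulated B16F10 libraries, a list raised on purpose had an adjusted p of 1.47e-29 with the preset and 0.00594 with the estimated correlation, and camera called 0 unchanged lists among the 26 tested with either. Genes were drawn independently of each other there, so this cannot show how the preset fares when the genes of a list vary together.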

Results

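Hypochlorous acid (HOCl) is the oxidant that myeloperoxidase of neutrophils makes from hydrogen peroxide and chloride. The series asked how 600 µM HOCl for 5 h changes the transcripts of B16F10 melanoma cells and of splenic CD8+ T cells. RNA sequencing gave 3 untreated and 3 HOCl libraries of B16F10 and 2 untreated and 1 HOCl library of T cells. The B16F10 libraries held 45.9 to 61.3 M gene counts and the untreated T cell libraries 49.9 and 52.1 M. The library labelled T cell HOCl held 12.8 M counts and stood apart from the other 8. It had a count for 44225 genes against 22855 to 25907 elsewhere. Mitochondrial transcripts took 37.4% of its counts (95% Wilson interval 37.4 to 37.5) against 1.55% and 2.11% in untreated T cells and 0.5003 to 0.711% in B16F10. Each comparison below is of HOCl against untreated.

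In B16F10 cells given HOCl, most NRF2 target genes and most ATF4 stress genes rose, and most interferon, DNA replication and cholesterol synthesis genes fell. These are counts of single genes: as lists they passed camera at its preset correlation, and 0 of 26 lists passed with an estimated one, where the smallest adjusted p was 0.0854. Mat2a, the catalytic subunit of methionine adenosyltransferase, rose 4.80-fold, from 413 ± 26.1 to 2021 ± 32.7 CPM (mean ± SD, n = 3 per group). Hmox1, which encodes heme oxygenase 1, rose 3.68-fold, from 115 ± 3.34 to 433 ± 23.7 CPM. Among the largest falls, the interferon-inducible GTPase gene Tgtp2 dropped from 13.6 ± 0.448 to 4.37 ± 0.551 CPM and the ETS factor gene Etv5 from 13.8 ± 1.11 to 4.84 ± 0.602 CPM. Of 16082 genes tested, 2366 rose and 2178 fell (28.3% in all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Most changes were small: the median absolute log2 fold change of these genes was 0.32, with 366 up and 352 down at least 1.5-fold, and 93 up and 112 down at least 2-fold.

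Mat2a (ENSMUSG00000053907, chromosome 6, 72432799 to 72439558, GRCm38) had a log2 fold change of 2.26 ± 0.05 (SE) and an adjusted p of 2.40e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) had 1.88 ± 0.05 and an adjusted p of 1.48e-09 by that edgeR test. Both calls ended with all 9 libraries in 1 fit, where 11 genes rose and 26 fell in all. The rest of the 8 largest rises were in low transcripts but for Chac1, whose product cleaves glutathione and which rose 2.79-fold, from 34.6 ± 1.88 to 98.6 ± 4.82 CPM. BC049762 went from 0.637 ± 0.170 to 3.17 ± 0.166 CPM, and Spi1, which encodes the myeloid factor PU.1, from 0.252 ± 0.0653 to 1.08 ± 0.147 CPM. The linker histone gene Hist1h1d rose 3.61-fold and the carboxylesterase gene Ces1a 3.08-fold, to 2.24 ± 0.361 and 1.07 ± 0.370 CPM. Fam169b reached 1.44 ± 1.76 CPM with an adjusted p of 0.0407 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1 HOCl library at 3.47 CPM carried most of it: without HOCl replicate 3 its adjusted p was 0.135.

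The largest fall was of Lims2 (ENSMUSG00000024395, chromosome 18, 31922290 to 31958619), a LIM-domain gene of focal adhesions, with a log2 fold change of -1.99 ± 0.22 from 2.74 ± 0.292 to 0.703 ± 0.155 CPM. Sptbn5, a spectrin gene, had -1.70 and Rassf4, a Ras-association domain gene, -1.42, both below 2 CPM. The immunity-related GTPase gene Iigp1 fell by 1.47 and Tgtp2 by 1.67 on the log2 scale, and Tgtp2 has a near-identical neighbour whose reads cannot be told apart from its own. Etv5 and Etv4, ETS factors downstream of receptor kinase signalling, fell by 1.53 and 1.45. Id3, an inhibitor of helix-loop-helix factors, fell from 69.3 ± 3.82 to 26.7 ± 6.82 CPM.

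Targets of NRF2, the factor that answers oxidants, rose in 19 and fell in 1 of 27 members tested (19 and 2 adjusted over the list alone), with a median log2 fold change of 0.32. The list passed camera, with an adjusted p of 4.15e-08 at the preset and adjusted p = 0.211 with an estimated correlation. Slc7a11, the cystine importer, rose 2.67-fold from 155 ± 25.3 to 422 ± 24.2 CPM. Gclm, a subunit of the enzyme that starts glutathione synthesis, rose 2.16-fold from 112 ± 6.76 to 245 ± 5.98 CPM. Srxn1, which repairs oxidised peroxiredoxins, rose 2.03-fold from 149 ± 3.00 to 309 ± 11.8 CPM. Txnrd1, cytosolic thioredoxin reductase, rose 1.31-fold to 680 ± 13.99 CPM. The exception was Tkt, transketolase of the pentose phosphate path, at a log2 fold change of -0.18 ± 0.05. That call ended without TMM and without any 1 library other than untreated replicates 1 and 2.

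Genes of the ATF4 integrated stress response, which meets amino acid shortage and misfolded protein, rose in 21 and fell in 0 of 26 members (22 and 1 adjusted over the list alone, median 0.54). Camera gave an adjusted p of 2.63e-12 at the preset and adjusted p = 0.188 with an estimated correlation. Trib3, a pseudokinase gene, rose 2.36-fold to 155 ± 16.1 CPM and Atf3, a stress-induced factor, 2.13-fold to 33.4 ± 0.854 CPM. Ddit4, an inhibitor of mTORC1, rose 1.91-fold from 73.5 ± 1.10 to 143 ± 1.18 CPM, and Ddit3, which encodes CHOP, 1.85-fold to 94.7 ± 1.16 CPM. Chaperones and degradation factors of the endoplasmic reticulum moved the other way, 12 lower and 3 higher of 20 (the same counts adjusted over the list alone, median -0.24, camera adjusted p = 0.00277 at the preset and adjusted p = 0.452 with an estimated correlation). Sdf2l1 fell by 0.55 and Pdia4 by 0.33 on the log2 scale, while Atf6, a sensor of unfolded protein, and Dnajb9 rose by 0.23 and 0.22. The latter pair lost their calls without HOCl replicate 2 or 3.

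Targets of p53, the DNA damage factor, rose in 12 and fell in 0 of 19 (12 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 7.82e-06 at the preset and adjusted p = 0.0854 with an estimated correlation). Gadd45a, a growth arrest gene, rose 1.98-fold to 41.5 ± 2.41 CPM, and Mdm2, the ligase that marks p53 for destruction, 1.47-fold from 178 ± 5.56 to 266 ± 8.65 CPM. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 1.14-fold, with an adjusted p of 0.0442 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; its call ended without any 1 library other than untreated replicate 1 (adjusted p 0.0865 to 0.145 without those). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, rose in 5 and fell in 0 of 15 (7 and 0 adjusted over the list alone, median 0.87, camera adjusted p = 0.00118 at the preset and adjusted p = 0.211 with an estimated correlation). Hist1h1c rose 1.83-fold to 50.9 ± 3.27 CPM and Hist1h2bc 1.40-fold to 41.5 ± 3.33 CPM.

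Interferon-stimulated genes fell in 18 and rose in 0 of 20 (18 and 0 adjusted over the list alone), with a median of -0.76, the lowest among the lists tested. Camera gave an adjusted p of 3.24e-12 at the preset and adjusted p = 0.157 with an estimated correlation. Ifit1, an antiviral RNA-binding gene, fell from 90.5 ± 8.98 to 48.2 ± 2.38 CPM, and Ddx58, which encodes the RNA sensor RIG-I, from 153 ± 5.96 to 90.2 ± 5.36 CPM. Class I antigen presentation genes fell in 7 and rose in 0 of 11 (9 and 0 adjusted over the list alone, median -0.33, camera adjusted p = 0.00382 at the preset and adjusted p = 0.5002 with an estimated correlation). Tap1, a peptide transporter gene, fell by 0.33 and Psmb8, an immunoproteasome subunit gene, by 0.72 on the log2 scale.

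DNA replication and S phase genes fell in 21 and rose in 0 of 22 (21 and 0 adjusted over the list alone, median -0.50). Camera gave an adjusted p of 3.29e-15 at the preset and adjusted p = 0.0854 with an estimated correlation. Mcm7, a subunit of the replicative helicase, fell from 196 ± 1.56 to 128 ± 1.66 CPM, and E2f1, a factor of S phase entry, from 89.0 ± 4.11 to 54.6 ± 1.62 CPM. Mitosis genes fell in 11 and rose in 0 of 20 (12 and 0 adjusted over the list alone, median -0.18, camera adjusted p = 0.000575 at the preset and adjusted p = 0.157 with an estimated correlation). Ccna2, cyclin A2, fell by 0.42 and Cdk1 by 0.36 on the log2 scale. Cholesterol synthesis genes fell in 16 and rose in 0 of 19 (17 and 0 adjusted over the list alone, median -0.32, camera adjusted p = 1.70e-08 at the preset and adjusted p = 0.211 with an estimated correlation). Mvd, a mevalonate pathway enzyme gene, fell from 92.4 ± 4.03 to 54.6 ± 2.50 CPM and Nsdhl from 78.2 ± 3.99 to 52.3 ± 1.09 CPM.

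Smaller shifts were seen in 4 further lists, each with adjusted p = 0.689 with an estimated correlation. Nuclear respiratory chain subunits fell in 8 of 22 (9 adjusted over the list alone, median -0.17, Uqcrfs1 -0.29 and Ndufs3 -0.24) and in 5 without TMM. Glycolysis genes fell in 5 of 15 (7 adjusted over the list alone, median -0.14), Hk1 and Ldha by 0.37 and 0.35 on the log2 scale. Proteasome subunits fell in 6 of 27 (4 adjusted over the list alone, median -0.13, Psma5 -0.30, Psmc4 -0.22). Of 28 cytosolic ribosomal protein genes, 1 fell, Rpl27 at -0.16 ± 0.05, and 0 did adjusted over the list alone or without TMM (median -0.13). Without HOCl replicate 3 the calls of Ndufs3, Psmc4 and Rpl27 ended. None of these lists had a riser, and camera's adjusted p at the preset were 0.00118, 0.0392, 0.00382 and 0.00277.

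**Figure D1:**
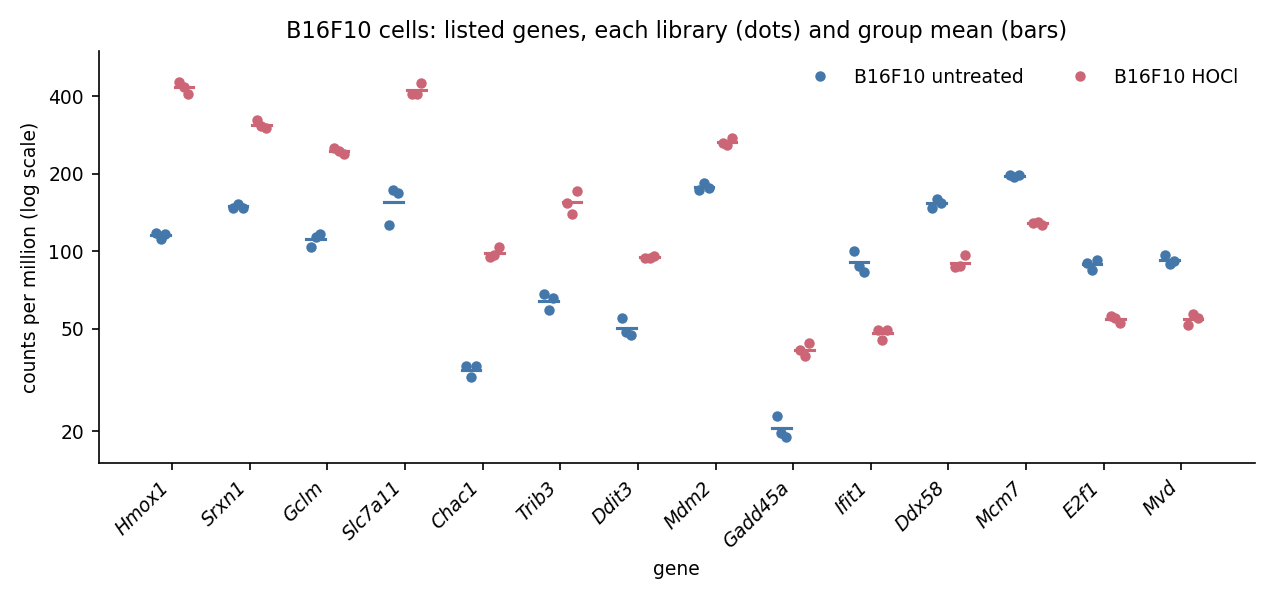
CPM (log axis) of 14 listed genes in B16F10 cells; dots are libraries, bars the mean of 3 untreated (blue) or 3 HOCl (red) libraries. HOCl libraries lie above untreated ones from Hmox1 (433 against 115) to Gadd45a and below them from Ifit1 (48.2 against 90.5) to Mvd, with no overlap.

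**Figure D2:**
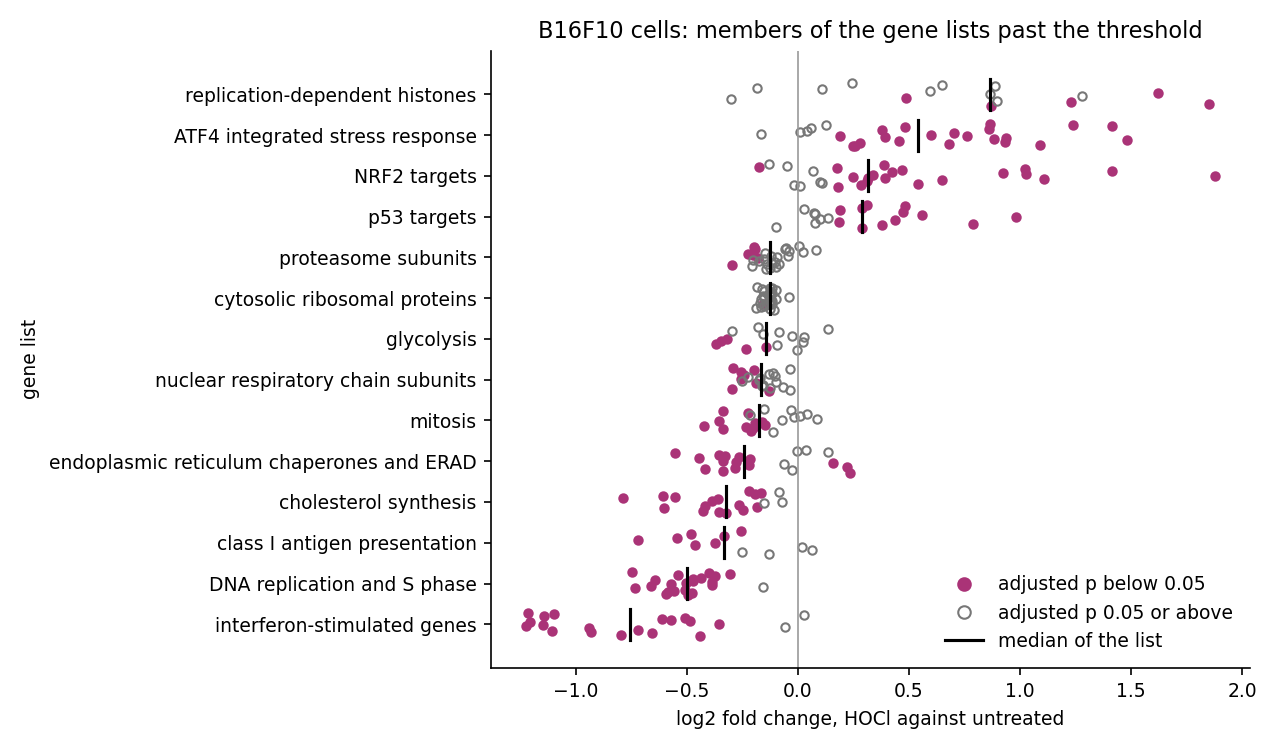
Log2 fold changes, HOCl against untreated, of the members of the 14 gene lists that passed camera at its preset correlation in B16F10 cells, of which 0 passed with an estimated one (smallest adjusted p 0.0854 over 26 lists); filled dots have an adjusted p below 0.05 and black bars are list medians. Medians run from -0.76 for interferon-stimulated genes to 0.87 for replication-dependent histones.

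Pigment genes did not pass camera (adjusted p = 0.0618 at the preset), with 1 higher and 4 lower of 16 (2 and 7 adjusted over the list alone, median -0.09). Mc1r, the melanocortin receptor gene, fell from 176 ± 10.3 to 112 ± 2.09 CPM; Tyr, tyrosinase, fell by 0.25 and Mlana by 0.23 on the log2 scale, and Sox10, a melanocyte lineage factor, rose by 0.28. Without HOCl replicate 2 or 3 the calls of Tyr and Mlana ended. Pmel stood at 5439 ± 208 CPM against 5539 ± 287, Dct at 7655 ± 182 against 7970 ± 243 and Mitf at 347 ± 7.63 against 351 ± 27.6. Heat shock targets had 2 higher and 5 lower of 21 (4 and 5 adjusted over the list alone), among them Hspb1 and Hspb8 up by 0.52 and 0.31 and Cacybp and Hspa8 down by 0.26 and 0.24. The list's median was -0.01 and its mean 0.04, and without TMM it had 5 higher and 4 lower and a median of 0.02. Hspa1a, Hspa1b and Dnajb1 had log2 fold changes of 0.70 ± 0.36, 0.24 ± 0.13 and -0.10 ± 0.05, none past the threshold, and the first pair are near-identical copies. In the metallothionein and zinc list, Slc30a1, a zinc exporter gene, rose 1.68-fold and Mtf1 1.33-fold, Mt1 fell by 0.27 and Mt2 had -0.12 ± 0.08, 2 higher and 1 lower of 5 (2 and 1 adjusted over the list alone, median -0.07, mean 0.14, camera upward). Mt1 lost its call without TMM and without any 1 HOCl library.

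Immediate early genes had 5 higher and 3 lower of 23 (8 and 3 adjusted over the list alone, median 0.13). Fos fell by 0.74 and Myc by 0.33 on the log2 scale, Fosl2 and Klf6 rose by 0.50 and 0.27, and Egr1 had 0.41 ± 0.15. NF-kB targets had 4 higher and 3 lower of 16 (5 and 3 adjusted over the list alone, median 0.11), with Birc3 and Tnfaip2 up by 0.51 and 0.50 and Cxcl10 and Irf1 down by 0.62 and 0.33. Nfkbia had 0.09 ± 0.09, and Tnfaip3 1.65 ± 0.70, at 3.33 ± 3.24 CPM against 1.03 ± 0.322 CPM in untreated cells, with 7.07 CPM in HOCl replicate 3. Hypoxia genes had 3 higher and 2 lower of 13 (3 and 2 adjusted over the list alone, median 0.03), Ddit4 and the oxidase gene Ero1l up by 0.94 and 0.81 and Car9 and Higd1a down by 0.51 and 0.30, and 5 higher and 2 lower without TMM. Higd1a lost its call without HOCl replicate 3 and Car9 without untreated replicate 2. Apoptosis regulators had 3 higher and 4 lower of 16 (4 and 4 adjusted over the list alone, median -0.01, 0.02 without TMM, mean 0.09, camera upward), Bmf and Mcl1 up by 0.60 and 0.30 and Bak1 down by 0.21. Mitochondrially encoded transcripts had 0 of 13 past the threshold by edgeR and 0 adjusted over the list alone; the smallest p was mt-Co2's, 0.0283 unadjusted, at -0.32 ± 0.13.

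The lists of other cells that were tested in B16F10 had 5 to 11 tested members. T cell identity genes had 0 of 8 past the threshold by edgeR (0 adjusted over the list alone, median 2.07, Lck 0.61 ± 0.25, unadjusted p 0.0315), and naive T cell genes 2 higher of 11 (2 adjusted over the list alone, median 1.79), Foxo1 and Foxp1 at 0.30 and 0.26, both lost without HOCl replicate 3. How far these medians rest on HOCl replicate 3 was not tested. That library held 227 T cell-only genes at a median of 0.750% of the untreated T cell level against 0.0765 to 0.1004% in the other B16F10 libraries. Macrophage markers had 0 of 5 past the threshold by edgeR (0 adjusted over the list alone; Cst3 -0.18 ± 0.07, unadjusted p 0.0183) and fibroblast markers 1 lower of 5 (1 adjusted over the list alone, median 0.03, mean -0.08, camera downward), Col1a1 at -0.64 ± 0.11. Lists too small to test here gave Havcr2 at -0.54 and Zbtb7b at 0.22, both lost without HOCl replicate 2 and Havcr2 also without TMM, and, not past the threshold, Ighm at 3.31 ± 1.82, Pecam1 at 1.21 ± 0.82, Tnfrsf4 at 0.37 ± 0.40 and Klf1 at 0.09 ± 0.40.

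Of the 26 lists, 14 passed camera at the preset correlation (4 up, 10 down), 13 passed fry, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.0854. Counts of genes fell to 28 up and 45 down when tested against a 1.5-fold change, and to 1432 and 1410 down without HOCl replicate 2 or 3. In the authors' deposited table for B16F10, 2385 genes had a positive and 2142 a negative log2 fold change past an adjusted p of 0.05; 4331 were called there and here, 100% of them with the same sign.

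The T cell comparison set 1 HOCl library against 2 untreated ones. In the library labelled T cell HOCl, T cell identity and naive T cell genes were lower, and pigment genes, mitochondrial transcripts and many genes silent in untreated T cells were higher. Il7r, the interleukin 7 receptor gene, stood at 76.5 CPM against 1542 ± 14.2 CPM (SD, n = 2) in untreated T cells, and Cd8a, which encodes the CD8 alpha chain, at 69.2 against 406 ± 65.9 CPM. Both calls ended with all 9 libraries in 1 fit. Mlana, a melanosome gene, stood at 321 against 2.01 ± 1.95 CPM. Of 32499 genes tested, 15639 were higher and 4838 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The spread of the HOCl arm was not measured but taken to be that of the 2 untreated libraries, so these calls describe 1 library. They came with a median log2 fold change over all tested genes of 3.14. Camera sets a list against those genes, so a list of genes expressed in untreated T cells can pass downward without having fallen. Of the higher genes, 95.6% were under 1 CPM in untreated T cells, 85.1% under 1 CPM in both untreated cell types, and 46.5% were protein coding, against 91.3% of the lower genes.

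**Figure D3:**
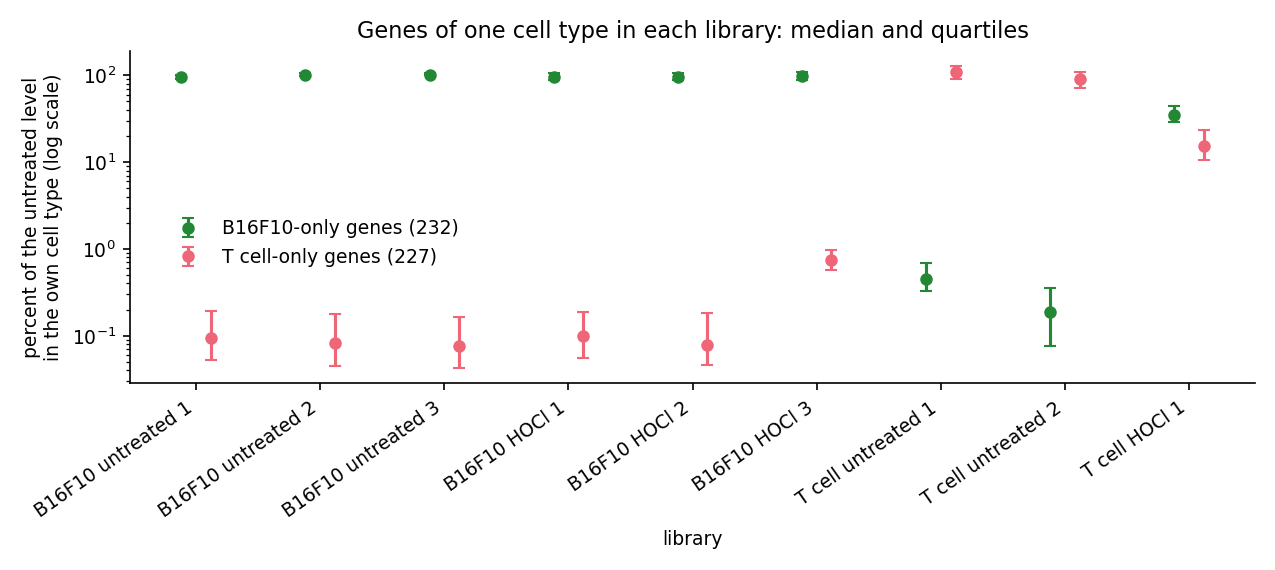
Median level, with quartiles, of 232 B16F10-only genes (green) and 227 T cell-only genes (red) in each library, as a percent of the mean untreated level in their own cell type (log axis). The T cell HOCl library holds both, B16F10-only genes at 35.3% and T cell-only genes at 15.5%. Neither share is corrected for counts of the kind that silent genes had in that library.

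The makeup of that library differed from any other. The 232 B16F10-only genes stood at a median of 35.3% (quartiles 29.3 and 44.6) of their untreated B16F10 level. In the untreated T cell libraries they stood at 0.453% and 0.190%, low by the choice of genes under 1 CPM there. The 227 T cell-only genes stood at 15.5% (quartiles 10.6 and 23.7) of their untreated T cell level. Neither share was corrected for counts of the kind that silent genes had in this library, so both may be too high. Olfactory and vomeronasal receptor genes, which are expressed mainly in sensory neurons, had a count for 1322 of 1459 against 67 to 274 in the other 8 libraries. Among the largest rises were those of genes at 0 in both untreated libraries, on the TMM scale: Cfap65 at least 369.9-fold, AW822073 367, Prtg 344, Hoxb1 339, Smok2a 323, Plxnb3 302 and Vmn2r4 292. Without TMM these bounds are 1.86 times higher. They include a cilia gene, a homeobox gene and a vomeronasal receptor gene, and Cfap65 (ENSMUSG00000047021, chromosome 1, 74902071 to 74935599) reached 40.4 CPM.

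T cell identity genes were lower in 17 of 17 (17 adjusted over the list alone), with a median log2 fold change of -3.43, or -3.26 and -3.54 against untreated replicates 1 and 2 alone. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) had -3.43 ± 0.78, a call that ended with all 9 libraries in 1 fit. It also ended without untreated replicate 2. As in every fit without 1 untreated T cell library, B16F10 alone gave the spread there, so such losses cannot be put down to the replicate. Cd3e, a chain of the T cell receptor complex, had -3.26, and Cd247, its zeta chain, -4.77. Both calls ended when T cell-restricted genes were scaled among themselves, a set chosen after seeing the data. Such scaling removes the shift shared by the set, so these losses say nothing against that shift. In CPM, Cd3e stood at 19.1% and Cd247 at 6.89% of the untreated level. Naive T cell genes were lower in 11 of 11 (11 adjusted over the list alone, median -4.02), among them Ccr7, a lymph node homing receptor, at -5.39, Il7r at -5.23 and S1pr1 at -4.98. With all 9 libraries in 1 fit, and without untreated replicate 2, Ccr7 and Il7r lost their calls, Il7r also without replicate 1. Both lists passed camera (adjusted p = 9.43e-09 and 6.96e-07 at the preset, adjusted p = 0.819 each with an estimated correlation). The T cell-only genes as a set stood at 15.5% of their untreated CPM in this library, with quartiles of 10.6 and 23.7 and no background taken off. That share is without TMM, where the median log2 fold change was -2.55 for T cell identity genes and -3.15 for naive T cell genes. Segments of T cell receptor and immunoglobulin genes were at 0 in it: Trbv17 at least 75.2-fold lower, Trbv31 50.9, Ighv2-2 28.7, Trav7-5 12.8, Ighv1-34 10.6, Trav13-4-dv7 10.2 and Igkv13-84 9.37. Nrarp, a Notch-regulated gene, was at least 23.5-fold lower, and without TMM these bounds are 1.80 to 1.88 times lower and the calls of Trav7-5, Ighv1-34, Trav13-4-dv7 and Igkv13-84 ended.

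Among activation and cytotoxicity genes, 1 was higher and 4 lower of 17 (1 and 4 adjusted over the list alone, median -0.92, camera adjusted p = 0.00809 at the preset, adjusted p = 0.819 with an estimated correlation). Cd69, an early activation marker, had -3.08 and Fasl -4.61, while Ccl3 had 3.94, and 1 was higher and 2 lower without TMM (median -0.02). Gzmb, granzyme B, had -2.09 ± 1.07 and Ifng 0.86 ± 1.84, neither past the threshold. Inhibitory receptors had 2 higher and 4 lower of 9 (2 and 4 adjusted over the list alone, median -1.28), Ctla4 and Pdcd1 at -3.38 and -2.79 and Havcr2 and Lag3 at 3.56 and 2.75. Without TMM they had 2 higher and 1 lower (median -0.38) and Pdcd1 lost its call, as it did without untreated replicate 2 and with all 9 libraries. NF-kB targets had 4 higher and 13 lower of 23 (4 and 13 adjusted over the list alone, median -2.30, camera adjusted p = 0.000378 at the preset, adjusted p = 0.819 with an estimated correlation, fry upward). Tnfaip3, a brake on NF-kB, had -5.93, Nfkbia -3.57 and Icam1 -3.94, with Vcam1 at 4.35 and Ccl2, at 0 in untreated T cells, at least 32.8-fold higher, and 6 higher and 10 lower without TMM. Immediate early genes had 2 higher and 11 lower of 24 (1 and 11 adjusted over the list alone, median -1.30, camera adjusted p = 5.35e-05 at the preset, adjusted p = 0.819 with an estimated correlation), Ier5 and Junb at -4.34 and -3.70, Egr2 and Egr3 at 3.28 and 3.70. Fos had -1.25 ± 1.02 and Egr1 -0.06 ± 1.11, the latter 0.84 without TMM. DESeq2's test ended the calls of Havcr2, Egr2 and Egr3. Gzmb and Fos passed without untreated replicate 1, where 1 T cell library was set against 1 with the spread of B16F10.

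Cytosolic ribosomal protein genes were lower in 28 of 28 (28 adjusted over the list alone, median -3.29, Rpl19 -3.39, Rpl30 -3.12), and in 17 without TMM. Class I genes were lower in 11 of 11 (11 adjusted over the list alone, median -2.65, Tap1 -3.71, Erap1 -2.998), and in 9 without TMM. Proteasome subunits were lower in 8 of 27 (7 adjusted over the list alone, median -1.18, Psmb1 -2.32, Psmd4 -2.08), and in 0 without TMM. Camera's adjusted p at the preset were 2.36e-08, 3.05e-06 and 4.52e-07 for these lists, each with adjusted p = 0.819 with an estimated correlation. Respiratory chain subunits were lower in 8 of 22 (5 adjusted over the list alone, median -0.999, Uqcrfs1 -2.26, Sdha -2.19), but 2 were higher and 0 lower without TMM (camera adjusted p = 0.000114 at the preset, adjusted p = 0.820 with an estimated correlation). Apoptosis regulators had 1 higher and 5 lower of 17 (1 and 5 adjusted over the list alone, median -1.21, camera adjusted p = 0.000120 at the preset, adjusted p = 0.819 with an estimated correlation, fry upward). Bcl2l11, which encodes the death factor BIM, had -4.60 and Mcl1, a survival factor, -3.41, and Hrk, at 0 in untreated T cells, was at least 27.8-fold higher. Without TMM 3 regulators were higher and 3 lower. Neither the stricter filter nor library totals without TMM left a call for Uqcrfs1, Sdha, Psmb1 or Psmd4.

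Medians of 5 lists changed sign without TMM. Those of the hypoxia and metallothionein lists also did between untreated replicates 1 and 2, at 0.06 and -0.50 and at -1.11 and 0.79. Endoplasmic reticulum chaperones had 0 higher and 7 lower of 20 (0 and 4 adjusted over the list alone; Herpud1 -2.11, Xbp1 -2.12), with a median of -0.71. Without TMM they had 2 higher and 0 lower and a median of 0.18. Targets of p53 had 4 higher and 5 lower of 20 (4 and 4 adjusted over the list alone), 5 higher and 4 lower without TMM, and medians of -0.85 and 0.04. Btg2 and Sesn1 had -4.43 and -3.63, Eda2r and Plk2 6.50 and 5.09, Cdkn1a 2.81 and Mdm2 -1.30 ± 0.62. Hypoxia genes had 0 higher and 2 lower of 13 (0 and 2 adjusted over the list alone; Pdk1 -2.64, Kdm3a -2.48), 1 and 2 without TMM, and medians of -0.32 and 0.65. Heat shock targets had 5 higher and 2 lower of 21 (3 and 2 adjusted over the list alone), 7 and 1 without TMM, medians of -0.58 and 0.33 and a mean of 0.32; Cryab and Hspb8 had 6.70 and 5.85, Dnajb1 and Chordc1 -2.36 and -2.002, Hspa1b 0.47 ± 0.87 and Hspa1a -2.38 ± 1.62. Metallothionein and zinc genes had 2 higher and 1 lower of 5 (2 and 2 adjusted over the list alone), with medians of -0.46 and 0.37 and a mean of 0.11; Mt2 and Mt1 had 3.65 and 2.72, and Slc30a1 -4.03. Camera's adjusted p at the preset were 2.61e-05, 0.000812, 0.0128, 0.0558 and 0.234 in that order; the first 3 had adjusted p = 0.819 with an estimated correlation. Herpud1, Xbp1 and Chordc1 lost their calls without TMM and with the stricter filter. Mdm2, Hspa1a and Hspa1b passed with either untreated replicate left out, but only with the spread of B16F10, as those fits set 1 T cell library against 1.

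NRF2 targets had 10 higher and 2 lower of 28 (10 and 1 adjusted over the list alone, median 0.94), with Srxn1 at 72.7 against 0.823 ± 0.621 CPM, Slc7a11 at 105 against 1.46 ± 0.275 CPM and Hmox1 at 84.5 against 5.09 ± 4.12 CPM. These genes were also abundant in untreated B16F10, at 149, 155 and 115 CPM. Gclc and Ugdh had -1.55 and -1.43, and Gclm 0.24 ± 0.59 and Txnrd1 1.08 ± 0.56 did not pass. Without TMM 15 were higher and 0 lower (median 1.82). ATF4 genes had 7 higher and 5 lower of 27 (6 and 5 adjusted over the list alone, median 0.17, or 0.77 and -0.19 against untreated replicates 1 and 2 alone). Gdf15 and Chac1 had 6.04 and 2.17, Cebpg and Ppp1r15a -3.45 and -3.14, Ddit3 -2.25, Atf3 0.55 ± 1.13 and Trib3 -1.18 ± 0.63, and without TMM 9 were higher and 2 lower (median 1.09). Trib3 passed the threshold in opposite directions without untreated replicate 1 (-1.49) and without replicate 2 (0.75). Atf3 gained a call without replicate 2, and Gclm and Txnrd1 did with either replicate left out. These fits set 1 T cell library against 1 with the spread of B16F10 alone, so such calls say nothing about the spread between T cell libraries. Without TMM and with the stricter filter the calls of Gclc, Ugdh, Ddit3, Gbp2 and Irf7 ended, and by DESeq2 that of Chac1. Interferon-stimulated genes had 4 higher and 2 lower of 20 (3 and 1 adjusted over the list alone, median 0.55): Rsad2 had 3.90, Ifi44, at 0 in untreated T cells, was at least 61.3-fold higher, and Gbp2 and Irf7 had -2.17 and -1.71. Without TMM 7 were higher and 0 lower (median 1.47). None of these lists passed camera, which sets a list against the other genes and pointed downward for each.

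Pigment genes were higher in 15 and lower in 0 of 17 (15 adjusted over the list alone, median 6.29, or 6.27 with genes at 0 set to their bound), with Mlana at 6.51 and Sox10 at 6.43; 13 abundant ones stood at a median of 27.4% of their B16F10 level. Mitosis genes, which dividing cells express, were higher in 19 of 20 (19 adjusted over the list alone, median 2.68, Cdk1 4.06, Tpx2 3.56). DNA replication genes had 5 higher and 3 lower of 22 (5 and 3 adjusted over the list alone, median 0.64, Tyms 3.14, Rrm2 3.14, Cdt1 -2.62, Mcm7 -2.52). Glycolysis genes had 4 higher and 1 lower of 15 (3 and 1 adjusted over the list alone, median 0.27, Hk2 4.06, Tpi1 3.35, Gpi1 -2.04). Cholesterol synthesis genes had 3 higher and 1 lower of 19 (3 and 1 adjusted over the list alone, median 0.19, Sqle 2.85, Srebf2 -2.12). Histones had 2 higher of 16 (2 adjusted over the list alone, median 0.57, or 2.63 and -0.15 against untreated replicates 1 and 2 alone; Hist1h2ac 6.00, Hist1h1d 5.08). Mitochondrially encoded transcripts were higher in 13 of 13 (13 adjusted over the list alone, median 3.85; mt-Atp6 3.88, mt-Co2 3.85). Without TMM the counts were 10 higher and 2 lower for DNA replication (median 1.51), 7 and 0 for glycolysis, 5 and 0 for cholesterol synthesis and 6 and 0 for histones, and the calls of Gpi1 and Srebf2 ended. None of these lists passed camera, with an adjusted p of 0.200 or more at the preset, and the B16F10-only genes stood at 35.3% of their B16F10 level in this library.

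Markers of other cells were tested in the same way. Fibroblast markers were higher in 7 of 7 (7 adjusted over the list alone, median 6.03, or 4.32 with the gene at 0 set to its bound; Col3a1 10.3 against 0.0768 CPM) and neutrophil markers in 7 of 10 (8 adjusted over the list alone, median 3.82, S100a8 5.24, S100a9 4.06). Macrophage markers were higher in 2 of 12 (1 adjusted over the list alone, median 1.15, Adgre1 5.48, C1qc 4.02) and erythroid markers in 2 of 8 (1 adjusted over the list alone, median 1.222, Slc4a1 4.94, Alas2 3.69). B cell markers had 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone, median 0.60, Ebf1 4.47, Pax5 3.78, Ighm -3.61), and natural killer markers 1 higher and 2 lower of 6 (1 and 2 adjusted over the list alone, median 0.36, Ncr1 4.64, Klrk1 -2.66, Klre1 -2.41). Endothelial markers had 2 higher and 1 lower of 5 (2 and 1 adjusted over the list alone, median 3.74, Kdr 5.07, Pecam1 -2.19), and of the CD4 list, too small to test, Cd4 had 4.94. Without TMM B cell markers had 7 higher and 1 lower, erythroid markers 3 and 0, natural killer markers 1 and 1 and endothelial markers 4 and 0, and the calls of Klre1 and Pecam1 ended. Leaving out untreated replicate 1 ended those of Ighm, Pecam1, Klrk1 and C1qc, and DESeq2's test those of C1qc and Alas2. None of these lists passed camera, and all stood in the library in which most receptor genes of sensory neurons also had counts.

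Of the 33 lists, 13 passed camera at the preset correlation, all downward, 12 passed fry, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.819. Without TMM the split was 17589 higher and 1928 lower (90.1% higher against 76.4% in the main test) and the median of all genes 4.04, or 3.28 with DESeq2's size factors. The stricter filter gave 3743 and 1705, and DESeq2's test 9956 higher. T cell-restricted genes scaled among themselves, a set chosen after seeing the data, gave 6 higher and 1 lower of 293. That scaling removes the shift its genes share. In the authors' deposited table for T cells, 10941 genes had a positive and 4326 a negative log2 fold change past an adjusted p of 0.05; 15243 were called there and here, 100% with the same sign.

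In the test of the interaction between HOCl and cell type, 10717 genes were more positive and 5119 more negative in T cells, of 34290 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The T cell HOCl arm was 1 library whose spread was not measured and in which B16F10-only genes stood at 35.3% of their B16F10 level, so these counts cannot be read as genes whose response to HOCl differed. Srxn1 rose 2.03-fold in B16F10 while its T cell value was larger by 5.11 ± 0.43 on the log2 scale, and Slc7a11's by 4.40 ± 0.28. Mt2 and Mt1 differed by 4.33 and 3.57 and Cdkn1a by 3.20, each more positive in T cells. Tnfaip3, Nfkbia, Ddit3, Dnajb1 and Mdm2 differed by -7.01, -3.11, -2.56, -1.71 and -1.32. No difference passed the threshold for Hmox1 (1.79 ± 0.66), Trib3 (-1.84 ± 0.77), Gclm (-0.33 ± 0.20), Hspa1b (0.76 ± 0.31), Fos (0.04 ± 0.42), Egr1 (0.08 ± 0.40) or Atf3 (0.03 ± 0.68). Atf3 passed it in opposite directions without T cell untreated replicate 1 (-0.86) and without replicate 2 (1.37). Trib3 and Hmox1 passed it with either left out, Gclm without replicate 1, and Hmox1 and Hspa1b without TMM and with the stricter filter. With either T cell untreated library left out, the spread came from B16F10 alone. The stricter filter gave 4560 more positive and 4022 more negative, and the replicate number as a block 6772 and 3931.

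Across the 15680 genes tested in both cell types, which are not independent replicates, the log2 fold changes had a Pearson r of -0.129 and a Spearman rho of -0.144. Genes higher in both numbered 295, where independent lists would share 495, and genes lower in both 497 against 626. Genes higher in B16F10 and lower in T cells numbered 1064 against 679, and the converse 588 against 456. The T cell log2 fold change was lower for genes with a higher untreated B16F10 level (r -0.330). All T cell values in these comparisons include the makeup of the single HOCl library.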

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

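All tests of the T cell HOCl library in this part were chosen after its values were seen, while the test of the difference between cell types was chosen before.

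The test of the difference between the cell types singled out 10717 genes with a more positive and 5119 with a more negative value in T cells, where the HOCl arm was 1 library of unmeasured spread. The most positive were Dgkb, a diacylglycerol kinase gene, at 17.12, Neurod2 at 16.66, Ccdc177 at 16.52, Unc45b at 16.47, Htr1a at 16.33 and Krt2 at 16.24. The most negative were Trbv17 at -13.70, Ighv2-2 at -13.08, Trav7-5 at -11.92, Ppbp at -11.30, Ighv1-11 at -9.93 and Trbv13-2 at -9.82. Each of these 12 rests on at least 1 group at or near 0, so the fitted values depend on the prior count and are no bound. Without B16F10 HOCl replicate 3 the calls of Trbv17, Ighv2-2, Trav7-5, Ppbp and Ighv1-11 ended.

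Among the stress genes the difference was 5.11 for Srxn1, 4.40 for Slc7a11, 4.33 for Mt2, 3.57 for Mt1, 3.20 for Cdkn1a, 1.26 for Chac1 and 1.22256 for Txnrd1. It was -7.01 for Tnfaip3, -3.11 for Nfkbia, -2.56 for Ddit3, -2.54 for Hspa1a, -1.71 for Dnajb1 and -1.32 for Mdm2. Each adjusted p was below 0.05 by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment, and each value includes the makeup of the single T cell HOCl library. Calls of Chac1 and Hspa1a ended with the replicate number as a block, and when single B16F10 libraries were left out.

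Melanocyte transcripts in the T cell HOCl library were weighed first. Induction of pigment genes in the T cells would leave other B16F10-only genes at their untreated T cell level, but with the background of silent genes taken off by exon length, 100% of the 229 outside the pigment list lay above 10 times it, which argues against it. The share was first taken with the background, also at 100%, but background alone would put 69.4% there, so it was taken again without. B16F10 RNA or reads in the library would raise all B16F10-only genes by a like share, and 100% of the 232 lay above 10 times their untreated T cell level in that way, at a median of 35.3% of the B16F10 level (quartile ratio 1.52), of which a median 15.2% was background. B16F10 RNA or reads may account for these transcripts, and the step at which they came in stays open.

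Silent nuclear genes and mitochondrial transcripts in the same library were weighed next. Lower depth would leave fewer genes with a count, yet 44225 had one in the shallowest of the 9 libraries. Genomic DNA may account for the silent genes: 90.6% of the receptor genes of sensory neurons had a count, and their counts ran with exon length (rho 0.52), while widespread low transcription was not tested and stays open. Mitochondrial DNA stays open too: the 6 mitochondrial mRNA genes differed 9.26-fold in CPM per kb, within the 5.65 to 11.5 of the other libraries, but the receptor genes were also uneven (quartile ratio 6.01), so evenness decides for neither. An effect of HOCl on the T cells stays open for both, since the study holds 1 such library.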

How the results depend on the processing

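Offsets for gene length and GC content, the T cell test without mitochondrial genes and that on T cell-restricted genes were chosen after seeing the data. The other alternatives were planned.

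Of 1474 values of B16F10 genes under alternatives, 1258 kept direction and side of the threshold, 188 lost the call, 21 gained one and 7 reversed. For T cell genes these were 1152, 84, 22 and 10 of 1268, and for differences 415, 30, 14 and 12 of 471. For lists they were 278, 22, 12 and 0 of 312 in B16F10 and 104, 20, 2 and 6 of 132 in T cells. Of 85 counts and correlations, 68 stayed within their bound (1.5 times a count, the 95% interval of a correlation, a bound set after the values were seen) and 17 did not.

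In B16F10, the test against a 1.5-fold change gave 28 higher and 45 lower, as most changes were smaller than that. All 9 libraries in 1 fit gave 11 and 26, where the 2 cell types share 1 estimate of the spread. Leaving out single libraries gave 1605 to 2819 higher and 1410 to 2634 lower. The replicate number as a block gave 2726 higher, 2567 lower and 15 lists, and 10703 genes that differed between cell types. With length and GC offsets, Pmel reversed to 0.00985 and Mt2 to 0.0485. Without single libraries, Ighm ran from -0.43 to 3.86, Pecam1 from -0.40 to 2.04 and Klf1 from -0.18 to 0.51. The first pair turned negative without HOCl replicate 3. The cause of these reversals was not tested.

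In T cells, library totals without TMM gave 1928 lower. The stricter filter gave 3743 higher and 1705 lower among 14632 genes, fewer than the 32499 tested otherwise. DESeq2 gave 9956 higher, and the cause was not tested. T cell-restricted genes gave 6 higher and 1 lower among 293, and in that set Klrk1 reversed to 0.36 and Pecam1 to 0.80, since scaling within it removes the shift shared by its genes. Egr1 reversed to 0.0833 with DESeq2's size factors, 0.84 without TMM, 0.86 with the stricter filter, 0.0834 by DESeq2, 0.48 with all 9 libraries and 0.31 and 0.45 without untreated replicates 1 and 2. Trib3 ran from -1.49 without untreated replicate 1 to 0.75 without replicate 2, both past the threshold, where each T cell group was 1 library assumed to vary like the B16F10 libraries. The cause was not tested.

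For the difference, the stricter filter gave 8582 genes of 13628 tested, fewer than the 34290 otherwise, 53.1% of them more positive. Gclm reversed to 0.00706 without TMM and 0.0238 with the stricter filter, and Atf3 to -0.0118 without a filter. Without single libraries, Atf3 ran from -0.86 to 1.37, Fos from -0.52 to 0.51 and Egr1 from -0.115 to 0.22, and the cause was not tested. The correlation across genes was -0.160 with the stricter filter and -0.144 by Spearman.

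With an estimated correlation, camera gave 0 lists in B16F10 and 0 in T cells, while fry gave 13 and 12. Fry asks for a shift on balance rather than against other genes. It reversed the T cell lists of NRF2 targets (adjusted p 0.0496) and of NF-kB targets, interferon-stimulated genes, DNA replication, apoptosis regulators and endothelial markers (adjusted p 0.0377 each). In B16F10, the glycolysis list lost its call without HOCl replicate 3 (0.144), without untreated replicate 1 (0.109) and by fry (0.108). Fry also ended those of nuclear respiratory chain subunits (adjusted p 0.117), proteasome subunits (0.194) and cytosolic ribosomal proteins (0.280). Depth limits the T cell HOCl library most, where a count of 0 allows up to 0.234 CPM.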

Other observations

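In this part, the offsets for length and GC content and the test on T cell-restricted genes were chosen after the result was seen, as was the bound for the planned test without untreated replicate 1.

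Of 293 T cell-restricted genes scaled among themselves, 6 were higher and 1 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 30 had an unadjusted p under 0.05. Higher were Dnah8, an axonemal dynein gene, at a log2 fold change of 2.76, Ptpn7 at 2.62 and Frat1 at 2.51. So were Cd74, the invariant chain of class II, at 2.91, Klra13-ps at 2.41 and Kcna2 at 2.25. Scaling within the set measures each gene against the others, so a gene that fell less than they did counts as higher. In plain CPM these 6 stood at 105% (Kcna2) to 180% (Cd74) of their untreated level. Lower was Ramp3, a receptor activity gene, at -3.59. At the 1.01 CPM per kb of silent autosomal genes in this library, a background by exon length would make up 67.9% of the CPM of Dnah8, 27.3% of Kcna2 and 13.7% of Ptpn7, 2.12 to 6.61% of Cd74, Frat1 and Klra13-ps, and all of Ramp3's 1.32 CPM. These genes were chosen after their values were seen.

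Among 6354 genes chosen for at most 10 counts over all the other libraries together, 5126 had a count in the T cell HOCl library. The 482 to 1224 with a count elsewhere are low by that choice. Pooled, they stood at 1.01 CPM per kb on autosomes and 0.956 on the X chromosome, against 0.00642 on the Y, where 4 of 182 had a count. Their median CPM per kb was 0.628 on autosomes and 0.469 on the X. How reads that map to several places were treated is not given, so the Y value need not mean that Y sequence was absent. The 1459 receptor genes had a median of 21 counts and 0.561 CPM per kb in the T cell HOCl library (quartiles 0.195 and 1.17). B16F10 HOCl replicate 3 held T cell-only genes at a median of 0.750% of the untreated T cell level, and Ighm at 15.5 CPM.

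The 4544 B16F10 genes past the threshold were weighed against 3 technical explanations. Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many genes, the real one, and the highest of the others gave 0 by edgeR, with 191 to 554 at an unadjusted p under 0.05; 10 splits are too few for a share under 0.05. Log2 fold changes ran with exon length (rho 0.24) and GC content (rho -0.15), but 93.6% of the genes were called in the same direction after offsets that brought these to 0.03 and 0.01. Without untreated replicate 1, 95.3% were. These values argue against either as the whole cause, and an effect of HOCl remains, as a hypothesis found and tested on the same data.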
